A study of Homo sapiens with 6 samples.

How the data were processed

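Total RNA of A549 cells was sequenced from 6 libraries, 3 of cells that received DMSO and 3 of cells that received 50 nM mitoxantrone, each for 48 hours. Per the labels' protocols, the DMSO was a 1/1000 dilution, the libraries were made with random priming and 13 PCR cycles, and reads were paired-end, 2x150 bases, from an Illumina HiSeq. The protocol names poly(A) selection or rRNA removal without saying which was used. It names no molecular identifiers and does not say whether the libraries kept strand. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

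The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 with no version, Cufflinks 2.2.1 and SAMtools 0.1.19. The genome build and annotation are not given in the sources used here. One table of the whole series was used. Per the file headers it gives, for each gene and library, a raw read count and an FPKM value (fragments scaled by gene length and library total). Per the file headers the authors also gave a mean normalized count over all libraries, a coverage-like signal made from counts divided by size factors. The authors' deposited log2 fold change and its standard error, a score that equals the fold change divided by that error, and a p-value with its adjusted p-value complete each row, with coordinates, symbol and annotation terms.

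The deposited table lists 4546 genes. The smallest absolute log2 fold change in it is 1.00 and the largest adjusted p is 0.0497, so it holds genes that passed a threshold on these same libraries. Ranks of the deposited p-values and adjusted p-values put the number of genes the authors tested near 22200 (median estimate from 20 genes) and the number past the adjusted p alone near 11800. A gene missing from the table is reported here as not listed, which does not mean unchanged. Of the identifiers, 4371 matched the gene name table, and 4 symbols that had been turned into dates were restored from their identifiers. A symbol was shared with another row in 8 rows, which were kept apart by identifier. Of 4390 identifiers also in GENCODE 29 (GRCh38), 37 had the same start or end there, so coordinates are given as the deposited table gives them and were not set against that annotation.

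Size factors were recovered by least squares from the raw counts and the authors' mean normalized counts, with a largest relative residual of 4.9e-10. They were 1.17, 1.08 and 1.16 for DMSO 1 to 3 and 0.827, 0.886 and 0.980 for mitoxantrone 1 to 3. Library totals were recovered from genes with an FPKM of at least 20 in the deposited FPKM columns, and for each library they varied by at most 0.05% over those genes. Normalized counts are raw counts divided by size factors, given as mean ± SD over the 3 libraries of a group. Fold changes are relative to the other transcripts of a library. No spike-in values were used here, so a change in total RNA per cell cannot be seen.

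The comparison was mitoxantrone against DMSO in edgeR 4.0.16 (R 4.3.3): a quasi-likelihood F-test on the raw counts with the recovered size factors, no covariate and no filter on low counts, with Benjamini-Hochberg adjustment over the 4546 genes and a threshold of 0.05. Log2 fold changes and standard errors (SE) come from this fit unless the authors' table is named. Because the genes had been chosen on these libraries, passing this second test is not independent evidence of change. The test was checked on 4546 simulated genes with the libraries' depths, of which 200 were changed, at a dispersion of 0.02. This is a wider spread than the coefficient of variation of 6.7% estimated for these libraries, so the shares recovered do not describe these data exactly. The test recovered 69% of the genes changed by 1 log2 unit and 91% of those changed by 2, with median estimates of 0.96 and 1.99. Of its calls, 4.8% were unchanged genes. Most simulated genes were unchanged, while every gene listed here had been selected for change, so this share does not carry over to these data.

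Before the data were examined, 16 gene lists, the design and the rule for named genes were fixed. The lists were p53 targets, DNA replication and G1/S genes, mitosis and G2/M genes, replication-dependent histones, double-strand break repair and Fanconi genes, senescence-associated secreted factors, antigen processing and MHC class I genes, interferon-stimulated genes, ligands of NK and T cell receptors, lysosome genes, cholesterol genes, NRF2 targets, lung epithelial genes, mesenchymal genes, leukocyte markers and cytosolic ribosomal protein genes. For each list the split of its listed members into higher and lower was set against that of all other listed genes by a two-sided Fisher's exact test, adjusted over the 15 lists with a listed member. Genes are not independent replicates, and genes of a list move together, so these p-values are too small. The other listed genes were not matched to a list by read count, with which the share of higher genes varies. A split that passes or fails may therefore reflect read count in part. The annotation terms in the deposited table with at least 10 listed genes, 434 in all, were tested the same way after the data were seen. Each term was set against all other listed genes, including those without a term (2941 listed genes had one). Set tests that compare a list with the whole transcriptome were not run, because only called genes are listed. The rule named, per direction, the 8 genes with the largest log2 fold change among those with a mean normalized count of at least 50 in the higher group and no overlap between groups. It also named the 3 members of each list with the smallest p, and always a fixed set that includes CDKN1A, MDM2, GDF15, LMNB1, TOP2A, TOP2B, MKI67, IL6, CXCL8, CD274 and BPIFA1. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen.

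The alternatives tried were TMM factors, column totals, DESeq2 1.42.0, a filter of at least 10 counts in at least 3 samples, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and a test against a 2-fold change. Library totals recovered from FPKM were added as a scaling after seeing the data. For a gene with 3 counts or fewer over a group, the ratio of normalized counts is given with its exact 95% interval, and a group at 0 is set at a floor of 3 counts over the group. Without molecular identifiers, such intervals and floors cover counting error only. Transcript GC content and 3' UTR sequences came from GENCODE 29, matched by identifier. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for summaries and figures.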

Results

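The transcriptome of A549 cells, an established human lung adenocarcinoma line, was measured by RNA sequencing after 48 hours with DMSO, the solvent control, or with 50 nM mitoxantrone, an anthracenedione that poisons DNA topoisomerase II. Each group had 3 libraries. The series title places the comparison in work on immunogenic senescence of lung cancer cells and on LUNX, a name of the secreted airway protein BPIFA1. The library totals recovered from the deposited values were 21781220, 20380674 and 21607331 reads for DMSO 1 to 3 and 16681380, 17491982 and 19352443 for mitoxantrone 1 to 3. The 4546 listed genes held between 3505621 and 3772454 of these reads in the DMSO libraries and between 2862983 and 3268896 in the mitoxantrone libraries, or 16.9% to 17.3% of each total.

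After mitoxantrone, genes of cell division were lower, by up to 162-fold (SKA1), and most of the listed p53 targets (27 of 28), lysosomal genes (21 of 21) and interferon-stimulated genes (19 of 21) were higher. MKI67, the proliferation marker, fell from 7312 ± 36.7 to 128 ± 11.5 normalized counts, a 56.9-fold difference. CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose 8.03-fold from 4311 ± 554 to 34600 ± 1201 (SD, n = 3 libraries per group). All 4546 listed genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05. Of these, 2677 were higher and 1869 lower with mitoxantrone, each in the direction of the authors' deposited table. The absolute log2 fold change exceeded the authors' by a median of 0.04. The gap was wider for some genes with few reads in 1 group. SKA1, with 9 reads over the mitoxantrone libraries, had -7.34 against the authors' -6.68, and RP3-326I13.1 had 7.13 against 5.82. In 4470 genes the groups did not overlap, where chance gives 10% of genes with 3 against 3. The genes had been selected on these libraries, so these counts do not measure what share of the transcriptome changed.

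The split into higher and lower genes varied with the read count. A mean normalized count under 10 in both groups was found for 527 of the higher and 80 of the lower genes. The 3610 genes with a mean of at least 10 over all libraries split into 1892 higher and 1718 lower, and the 2623 genes with a mean of at least 50 into 1181 higher and 1442 lower. All 3 DMSO libraries had 0 reads for 219 genes, and all 3 mitoxantrone libraries for 28. Protein-coding genes made up 2048 of the higher and 1514 of the lower genes, long intergenic RNAs 167 and 69, and antisense RNAs 161 and 75. The edgeR biological coefficient of variation between replicates was 6.7%. Principal components were computed on the listed genes with a mean normalized count of at least 50. The first component held 98% of the variance and separated the groups. These genes had been selected for a difference between the groups, so that share does not describe the transcriptome. On the second component, with 0.7%, mitoxantrone 1 lay at -8.8 and mitoxantrone 2 and 3 at 4.8 and 4.3.

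The mitosis list fell almost as a whole. Of its 60 genes 59 were listed, all 59 lower, with a median log2 fold change of -4.90, and the remaining gene, BUB3, was not listed. TOP2A (ENSG00000131747), which encodes the topoisomerase II alpha that mitoxantrone poisons, dropped from 14810 ± 737 to 368 ± 35.1 normalized counts, 40.1-fold (log2 fold change -5.33 ± 0.08 SE; adjusted p = 2.2e-39). It lies at 38544768 to 38574202 on chromosome 17 as the deposited table gives it, with no build named. MKI67 (ENSG00000148773; chromosome 10, 129894923 to 129924649) had a log2 fold change of -5.83 ± 0.09, and TPX2, a spindle assembly factor, fell by 4.33 on the log2 scale, from 5327 to 264.5 counts. LMNB1, which encodes the nuclear lamina protein lamin B1 and is often low in senescent cells, was 9.02-fold lower (1642 ± 133 against 182 ± 15.1; adjusted p = 2.5e-29). The split of this list differed from that of the other listed genes (Fisher's exact test, adjusted p = 1.5e-22). All 59 also passed edgeR's test when adjusted over the list alone. Every one of the 4546 listed genes had an unadjusted p under 0.05 in that test. Adjusting over a list alone could therefore fail no member of any list, and it adds no evidence here or below.

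DNA replication and G1/S genes were also lower, 41 of the 43 listed out of 48, with a median of -2.46 (split adjusted p = 2.8e-13; 43 passed adjusted over the list alone). RRM2, the regulated subunit of ribonucleotide reductase, was 29.9-fold lower, TK1, thymidine kinase, 19.5-fold lower and MCM5, of the replicative helicase, 8.63-fold lower. The exceptions were PCNA, the sliding clamp of DNA polymerases, at a log2 fold change of 1.13 ± 0.06, and CCNE1, cyclin E1, at 1.03 ± 0.11. Of the double-strand break repair and Fanconi list 22 of 42 genes were listed and all 22 were lower, with a median of -3.35 (split adjusted p = 1.5e-08; 22 passed adjusted over the list alone). BRCA1 was 14.0-fold, FANCI 8.69-fold and the resection nuclease EXO1 38.5-fold lower. TOP2B, the other topoisomerase II gene, was not listed.

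**Figure D1:**
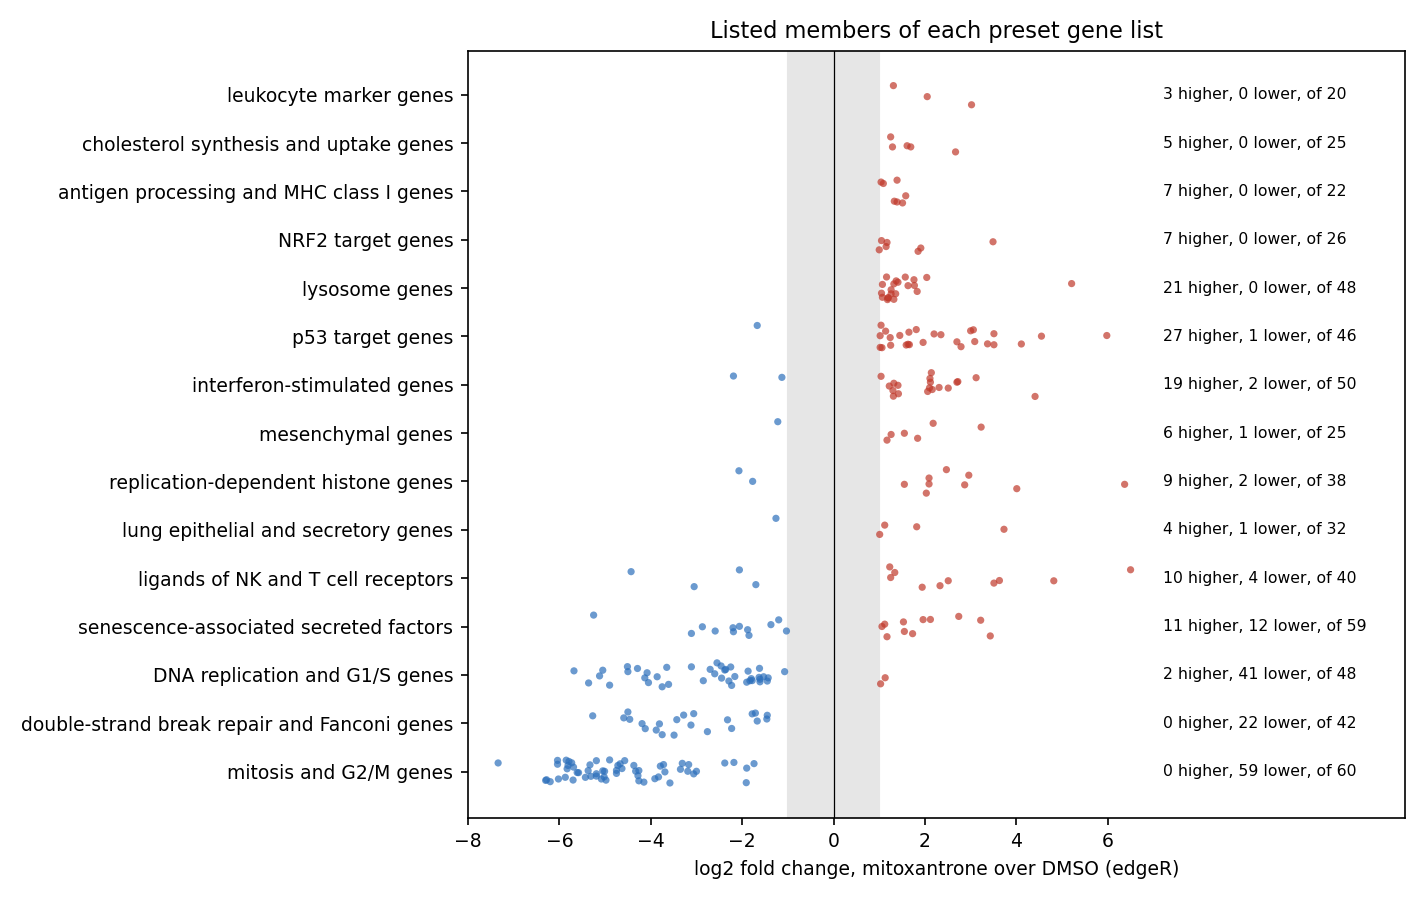
Log2 fold change of mitoxantrone over DMSO (x axis, edgeR) for each listed member of the preset lists (rows, 1 point per gene, spread vertically for sight only). Red points are higher and blue points lower with mitoxantrone, the grey band marks the range from -1 to 1 that the authors' threshold leaves out, and the text gives the members higher, lower and in the whole list, with 0 higher and 59 lower of 60 for mitosis.

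Among p53 targets, 27 of the 28 listed genes were higher, with a median of 1.96, of 46 in the list (split adjusted p = 3.2e-05; 28 passed adjusted over the list alone). CDKN1A (ENSG00000124762; chromosome 6, 36644305 to 36655116 as the table gives it) rose 8.03-fold (SE of the log2 fold change 0.07; edgeR, adjusted p = 2.9e-33). MDM2, a ubiquitin ligase gene, rose 4.58-fold from 1549 ± 147 to 7097 ± 968, FDXR, ferredoxin reductase, 8.36-fold, and TP53INP1 17.3-fold. TRIM22 was among the 8 largest rises of genes with a mean of at least 50 in the higher group and no overlap between groups, from 4.96 ± 1.67 to 323 ± 11.6 normalized counts, a log2 fold change of 5.98 ± 0.21. GADD45A went against the list, at -1.67 ± 0.07. The annotation term for p53-mediated intrinsic apoptosis, tested with the other terms after the lists, split into 6 higher and 4 lower (Fisher's exact test, adjusted p = 1 over 434 terms). GDF15 was not listed.

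Most of the listed histone genes were higher. Of 38 replication-dependent histone genes 11 were listed, 9 higher and 2 lower (HIST1H1D at -2.07, or -2.93 without mitoxantrone 3, and HIST2H2AC at -1.77), a split that did not differ from that of other listed genes (adjusted p = 0.33; 11 passed adjusted over the list alone). HIST1H2BK rose 7.32-fold, HIST1H2BD 5.53-fold and HIST1H2BC 16.1-fold. Histone genes are near-identical copies, so reads may be assigned among them with error, and their usual transcripts lack a poly(A) tail, so the unstated RNA selection bears on these values.

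The secreted factors linked to senescence moved both ways. Of 59 genes 23 were listed, 11 higher and 12 lower (adjusted p = 0.34; 23 passed adjusted over the list alone). IL11 fell by 5.25 on the log2 scale, from 8046 ± 1633 to 213 ± 24.2 counts, the growth factor gene EREG was 8.62-fold lower, and the protease inhibitor gene SERPINE2 rose 6.68-fold from 1870 ± 63.1 to 12500 ± 417. IL6 (chromosome 7, 22765503 to 22771621) was low in both groups and lower with mitoxantrone, 27.8 ± 10.1 against 5.95 ± 1.70 (log2 fold change -2.20 ± 0.42; edgeR, adjusted p = 7.8e-06), from 94 and 16 reads over the groups. CXCL8 was not listed. Other members that were higher were IL1B (3.43, or 4.40 without DMSO 2), MMP7 (3.22) and CXCL1 (1.73), and others lower were CCL20 (-2.59, or -4.58 without mitoxantrone 1), CXCL2 (-2.19) and IL1A (-1.88, all log2 fold changes).

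Interferon-stimulated genes were mostly higher, 19 of the 21 listed out of 50, with a median of 2.11 (split adjusted p = 0.0072; 21 passed adjusted over the list alone). The RNA-sensing synthetase gene OAS1 rose 6.57-fold from 98.7 ± 27.5 to 648 ± 3.70, ISG15 4.36-fold and LGALS3BP 4.17-fold. TMEM173, which encodes STING, was higher at 2.70, from a mean of 5.61 normalized counts to 37.1. The exceptions were MB21D1, which encodes the DNA sensor cGAS (-2.19), and ISG20 (-1.13). Related annotation terms did not pass: type I interferon signaling had 12 higher and 4 lower (adjusted p = 0.38 over 434 terms), interferon-gamma-mediated signaling 11 and 5 (0.66), defense response to virus 29 and 10 (0.15) and innate immune response 67 and 32 (0.19).

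All 7 listed genes of antigen processing and MHC class I, of 22, were higher, with a median of 1.39, but their split did not pass (adjusted p = 0.087; 7 passed adjusted over the list alone). The annotation term for presentation of peptide antigen via MHC class I had 11 higher and 0 lower, which passed (adjusted p = 0.021 over 434 terms). CALR, the endoplasmic reticulum chaperone calreticulin, rose 2.62-fold from 5286 ± 273 to 13870 ± 313, PSMB8, an immunoproteasome subunit, 2.85-fold and TAPBP, tapasin, 2.06-fold. TAPBP did not pass a test against a 2-fold change (glmTreat in edgeR, adjusted p = 0.12). B2M, which encodes beta-2 microglobulin, was not listed.

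Ligands of NK and T cell receptors split into 10 higher and 4 lower of the 14 listed out of 40 (adjusted p = 0.45; 14 passed adjusted over the list alone). CD274, which encodes the checkpoint ligand PD-L1, fell 8.30-fold from 201 ± 48.9 to 24.1 ± 0.394 normalized counts (chromosome 9, 5450503 to 5470566; edgeR, adjusted p = 7.9e-18). ULBP1, a ligand of the activating receptor NKG2D, fell 21.5-fold, while ULBP2 was higher at a log2 fold change of 1.25. TNFSF9, the ligand of 4-1BB, rose 11.4-fold from 73.9 ± 4.64 to 848 ± 56.9, and CD70 5.04-fold. TNFSF14, known as LIGHT, rose from 5 reads over the DMSO libraries to 386 over the mitoxantrone libraries (log2 fold change 6.50 ± 0.34, or 7.14 without DMSO 1).

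**Figure D2:**
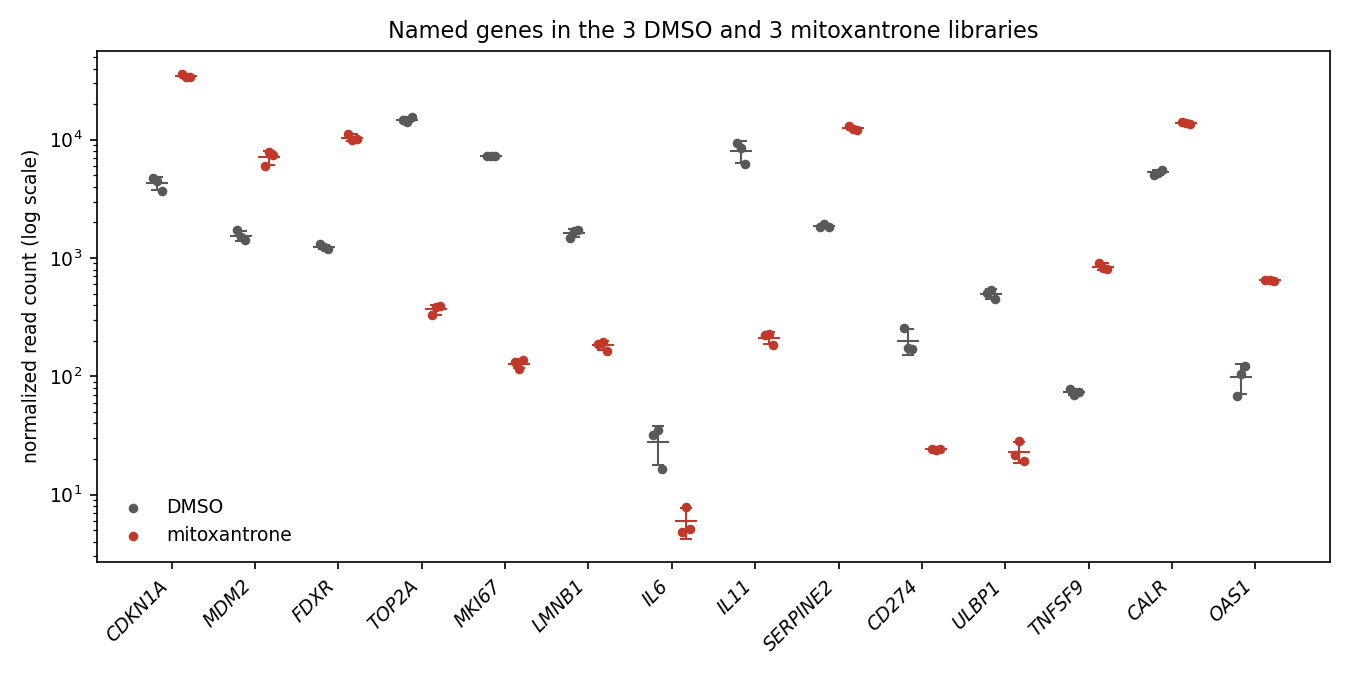
Normalized read counts (y axis, log scale) of 14 genes in the 3 DMSO (grey) and 3 mitoxantrone (red) libraries, with points for libraries, a horizontal mark for the group mean and bars for 1 SD. The groups do not overlap for any gene drawn. CDKN1A lies at a mean of 4311 against 34600, and MKI67 at 7312 against 128.

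The listed lysosome genes all rose, most by modest amounts. All 21 listed of 48 were higher, with a median of 1.32, which was the same with ATP6V0D2, at 0 reads with DMSO, set at its bound (split adjusted p = 5.3e-05; 21 passed adjusted over the list alone). The other 27 were not listed, and every listed gene had passed the authors' threshold. This median therefore does not describe the whole list. The protease genes CTSB and CTSD rose 2.96-fold and 2.58-fold, to 16690 ± 854 and 8873 ± 547 counts, and MAN2B1, a lysosomal mannosidase gene, 3.08-fold. The 5 listed cholesterol genes of 25 were all higher, with TM7SF2 at 6.37-fold and FDFT1 at 2.37-fold (split adjusted p = 0.14; 5 passed adjusted over the list alone). The 7 listed NRF2 targets of 26 were also all higher, with GPX2 at 11.2-fold, HMOX1 at 3.75-fold and AKR1C1 at 3.61-fold (split adjusted p = 0.087; 7 passed adjusted over the list alone). None of the 47 cytosolic ribosomal protein genes was listed.

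Epithelial and mesenchymal genes were both mostly higher where listed, and neither split passed. Of 32 lung epithelial and secretory genes 5 were listed, 4 higher (split adjusted p = 0.65; 5 passed adjusted over the list alone). KRT19 rose 13.2-fold, KRT8 2.17-fold from 63450 to 137500 counts, and CDH1, E-cadherin, 2.02-fold, which did not pass the test against a 2-fold change (glmTreat, adjusted p = 0.21), while MUC5AC was lower at -1.26. BPIFA1 was not listed, so nothing is known here of its level. Of 25 mesenchymal genes 7 were listed, 6 higher (split adjusted p = 0.34; 7 passed adjusted over the list alone), with ACTA2 at 9.41-fold, S100A4 at 4.53-fold and FN1 at 2.92-fold. COL1A1 was lower at -1.22. Of 20 leukocyte markers 3 were listed, all higher (split adjusted p = 0.34; 3 passed adjusted over the list alone): ITGAX from 15.9 ± 7.38 to 132 ± 12.7, CD14 from 23.9 ± 4.08 to 99.0 ± 5.92 and CD8A from 9.62 ± 3.22 to 24.4 ± 5.57 normalized counts. CD8A did not pass the test against a 2-fold change (glmTreat, adjusted p = 0.084).

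The largest rises among genes with at least 50 counts in the higher group included several non-coding genes. The intergenic RNA RP3-326I13.1 (chromosome X, 43036243 to 43085847) went from 3 to 381 reads over the groups, a ratio of 160 with an exact 95% interval of 54.5 to 782 (fitted log2 fold change 7.13, or 7.94 without DMSO 1). RP11-311F12.2 (log2 fold change 6.54 ± 0.34, or 8.02 without DMSO 3) is annotated antisense to ALDH3A1, an aldehyde dehydrogenase gene. ALDH3A1 was itself 9.66-fold higher and reached 93830 counts. The spans of these genes overlap in part, so without strand reads over the overlap cannot be told apart. SLC52A1, a riboflavin transporter gene, rose by 5.86 ± 0.18, CYGB, cytoglobin, which overlaps the listed gene PRCD, by 5.58 ± 0.18, the pseudogene IGFL1P1 by 5.65 ± 0.30 and LY6D by 5.58 ± 0.39. The largest falls included genes of the spindle and kinetochore, with SKA1 at -7.34 ± 0.21 (561 ± 3.99 to 3.33 ± 1.07 counts), DEPDC1 at -6.75 ± 0.18, KIF18B at -6.70 ± 0.13, NUF2 at -6.30 ± 0.21, KIF2C at -6.28 ± 0.13, CKAP2L at -6.20 ± 0.16 and the helicase gene PIF1 at -6.15 ± 0.25 (-6.93 without mitoxantrone 3). FUT1, a fucosyltransferase gene, went from 349 to 3 reads, a ratio of 92.1 (exact 95% interval 31.2 to 449); its fitted log2 fold change was -6.38, or -7.18 without mitoxantrone 3. By GENCODE 29, NUF2 overlaps RGS5, DEPDC1 overlaps DEPDC1-AS1, IGFL1P1 overlaps IGFL2-AS1 and ACTA2 overlaps FAS and STAMBPL1, all listed and on the opposite strand. TOP2A, CTSD and MAN2B1 overlap other listed genes. For all these genes, the gene of origin of reads over the overlaps is uncertain.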

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

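Library totals as scaling were chosen after seeing the data; the other alternatives were planned. Replacing the size factors moved every gene by -0.26 log2 (TMM on the listed genes), -0.09 (library totals) or -0.07 (column totals), and no call changed sign under any alternative. Of 910 values of the 65 named genes under alternatives, 907 kept their direction and side of the threshold and 0 reversed. The other 3, all in the test against a 2-fold change, were TAPBP (adjusted p = 0.12), CDH1 (0.21) and CD8A (0.084). Calls were 2676 higher and 1869 lower with TMM, 2655 and 1868 with DESeq2, 2654 and 1868 at an adjusted p of 0.01, 2204 and 1460 against a 2-fold change, and 4495 to 4533 in all with 1 library left out. With at least 10 counts in at least 3 samples, 3710 genes were tested and 1945 were higher and 1765 lower, so the share higher was 52.4% in place of 58.9%. Same-numbered libraries did not deviate together (correlations over 2622 genes of -0.07, -0.08 and 0.03), and the replicate block gave 4546 calls and changed none. Of 378 counts of calls and list members under alternatives, 3 moved by over 1.5 times: against a 2-fold change, replication members higher went from 2 to 1 and interferon members lower from 2 to 1, and with the count filter histone members lower went from 2 to 1. In each the stricter threshold or the removal of a low gene is the cause. Because every listed gene was selected on these libraries, stability here says little of genes near the authors' threshold. Set tests and pseudocounts, planned for other file contents, were not run. Depth limits most the 607 genes with a mean under 10 counts in both groups.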

Other observations

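The gene lists in this part other than those fixed before the data were examined, the annotation terms shown, and the tests of other library splits, of GC bias of the libraries and of gene span were chosen only after results were seen. Among 434 annotation terms with at least 10 listed genes, 31 had more higher and 76 more lower genes than all other listed genes (Fisher's exact test, adjusted p of 0.05). Genes of cell adhesion were higher in 114 of 134 cases (adjusted p = 1.8e-09) and those of extracellular matrix organization in 66 of 77 (8.1e-06), including FBN1, fibrillin-1 (11.8-fold), and MMP7 (9.29-fold). All 10 listed genes of keratinization were higher (0.032), among them ABCA12, from 29.7 ± 0.351 to 698 ± 12.1 counts, and HRNR, hornerin, from 25.5 to 289, but the related terms keratinocyte differentiation (6 higher, 9 lower; 0.35) and epidermis development (20 higher, 5 lower; 0.12) did not pass. Other members had few reads: LCE1E went from 0 to 11.8, LCE3E from 0 to 5.7 and LCE3D from 1.74 to 28.8 mean normalized counts. A gene at 0 with DMSO can be listed only as higher, so selection fixed part of this split. Filaggrin, FLG, rose 34.2-fold and complement C3 10.1-fold. The 18 clustered protocadherins listed under homophilic cell adhesion, a term with 40 genes higher and 3 lower, were all higher, with no test of their own, but they share exons, so counts of single members are uncertain. Genes of mRNA splicing were lower in 19 of 21 cases (5.3e-05) and of rRNA processing in 14 of 15 (3.4e-04), as were those of the broader terms RNA splicing (7 higher, 26 lower; 1.9e-04) and mRNA processing (7 and 21; 0.0026), while RNA metabolic process (9 and 15; 0.11), mRNA metabolic process (8 and 13; 0.18) and RNA processing (3 and 8; 0.16) did not pass. All 10 listed genes of tRNA aminoacylation were lower (0.0011), and 9 of them are also in the list of ATF4 targets.

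Of 16 cytosolic heat shock and chaperone genes 10 were listed, all higher (Fisher's exact test, adjusted p = 0.011 over 6 such lists). This list and the others of this paragraph were put together after values were seen, so their p-values are no independent evidence. The annotation terms protein folding (18 higher, 9 lower, adjusted p = 0.64) and response to unfolded protein (11 and 3, adjusted p = 0.33) did not pass. HSPA8 rose from 3248 ± 395 to 39910 ± 1138 counts, 12.3-fold, HSPB1 3.41-fold and HSP90AA1 2.59-fold. HSPA1A rose 22.7-fold and HSPA1B 18.9-fold, but these are near-identical copies. Early response transcription factors were lower in all 13 listed of 16 (adjusted p = 1.9e-05), with EGR1 at 59.2-fold, JUNB at 4.08-fold, MYC at 4.08-fold and JUN at 3.41-fold. Of 10 genes used as readouts of ERK signalling 8 were listed, 6 lower and 2 higher (adjusted p = 0.086), the latter CCND1 (1.69) and EPHA4 (2.29). TERT, the telomerase reverse transcriptase gene, was lower, 109 ± 9.57 against 6.62 ± 6.31 counts (log2 fold change -4.01, or -4.99 without mitoxantrone 2). The mitochondrial transcripts MT-ND5, MT-ATP6 and MT-ATP8 were higher at 1.22, 1.01 and 1.10.

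The real split of the 6 libraries called 4546 genes and the highest of the other 9 splits called 0 (edgeR at an adjusted p of 0.05, with at most 3 genes at an unadjusted p under 0.05). As large a result came from 1 of 10 splits, the real one, and 10 splits are too few for a share under 0.05. The genes had also been selected on the real split. Every other split mixes DMSO and mitoxantrone libraries in a group, so the difference between treatments counts as spread and few calls could arise.

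Targets of ATF4, the transcription factor of amino acid shortage and endoplasmic reticulum stress, were lower in all 39 listed of 51, with a median of -2.26, unchanged with FGF21, at 0 reads with mitoxantrone, at its bound. The list was put together after values were seen, so its p (Fisher's exact test, adjusted p = 2.1e-15) is no independent evidence, and the annotation terms endoplasmic reticulum unfolded protein response (8 higher, 10 lower; 0.41), amino acid transport (4 and 10; 0.094) and cellular amino acid metabolic process (4 and 6; 0.53) did not pass. TRIB3 fell from 19670 ± 1059 to 866 ± 67.1 counts, ASNS 17.2-fold, PHGDH 23.5-fold and DDIT3 fell by 3.33 on the log2 scale, and ATF4 itself from 9957 ± 362 to 4218 ± 197; ULBP1 and VEGFA are also in this list. In 10000 draws of listed genes with matched GC content, a mean of 37.5% of the genes were lower (95% range of draws 23.1% to 51.3%), against all 39 observed, but with members picked after values were seen this does not exclude GC content. A candidate explanation that also stays open is medium run low by denser DMSO cultures, which may raise these genes in the controls. Of 6 listed genes induced by low oxygen or glucose 33.3% were lower, against 41.1% of other listed genes (Fisher's exact test, p = 1). These 6 genes are too few to decide, and they were not chosen to read amino acid shortage. Less ATF4 activity with mitoxantrone is also open.

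Of 348 listed genes annotated to DNA-templated transcription 280 were lower (80.5%; adjusted p = 2.5e-52), and of 110 genes with a ZNF symbol, most of them zinc finger proteins, 100 were lower. Related zinc finger genes can share reads. In GC-matched draws a mean of 43.8% of the genes were lower (38.9% to 48.5%), against 80.1% of the 342 members with a GC value. The odds ratio of the annotation for lower was 8.67 (6.38 to 11.77) without genes of the cell cycle, replication and repair, and 6.33 (4.65 to 8.64) with the density of ATTTA, a motif of unstable mRNAs, and the length and GC of the 3' UTR in the model, from 6.25 without these terms (304 of 342 genes searched). These values argue against each as the whole cause. The term was picked after values were seen, however, and neither the draws nor the models were matched for read count. A biological response of this class, such as loss of short-lived mRNAs by a route other than ATTTA, may be involved, but mRNA half-lives were not tested.

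Listed genes lower with mitoxantrone had a median transcript GC content of 44.8% and those higher 53.4%. Without genes of the cell cycle, replication and repair the difference was 8.3 percentage points (7.4 to 9.3) in place of 8.6, which argues against the cell division programme as its whole source. The slope between the groups was 0.77 log2 per 10 percentage points of GC, against at most 0.152 between replicates of a group. A GC bias between library sets cannot be told apart from the treatment, since the groups hold different libraries and only selected genes are listed, and it may add to any change. The GC content of the mitosis and p53 lists, the preset lists tested for this, does not alone account for their direction: in GC-matched draws a mean of 50.5% of the genes were lower (39.0% to 62.7%) for the mitosis list, where all 59 were, and a mean of 57.7% were higher (39.3% to 75%) for the p53 list, observed 96.4%.

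Long genes were tested because stalled topoisomerases might block their transcription. Of protein-coding genes among the longest 20% by genomic span (at least 98.3 kb) 39.0% were lower, against 43.4% of the others (Fisher's exact test, p = 0.034). From the shortest to the longest of 5 equal groups, however, 35.5%, 41.7%, 47.3%, 49.0% and 39.0% were lower, so the share increased with span before it fell in the longest group, and the hypothesis stays open.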
